A study of Mus musculus with 9 samples.

How the data were processed

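The series measured TWIST1 occupancy by ChIP-seq in mouse embryoid bodies after 3 days of differentiation and 16 h of doxycycline. Groups were taken from the sample titles: 4 Twist1-OE ChIP, 2 Twist1-KO ChIP, 1 Twist1-KO input and 2 Twist1-OE inputs. The antibody was against TWIST1, per the labels, chromatin was formaldehyde-crosslinked and sonicated, and libraries were made with a TruSeq ChIP kit. Per the submitters' processing notes, Trimmomatic, BWA, Picard and MACS2 were used with the builds mm10 and GRCm38.p5. Their versions, their settings and the control given to the peak caller are not given in the sources used here. How the caller's control was chosen, and whether it was the same for every library, can change which peaks are listed and how high their fold is.

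The deposited files are MACS2 peak lists, 1 per library, so peaks were called per sample and not on pooled samples. Each peak has a fold enrichment over local background, a linear ratio made by the authors' caller. The authors' caller also gave −log10 of the p-value and of the q-value, and every deposited q-value was at most 0.01. The deposited score column, a rounded multiple of the −log10 q-value, was used only to check the layout. Fold values were used to describe and rank peaks within a list, and folds of different libraries stand side by side only as a description, since their lists have different depths.

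Lists were read with Python 3.11.15, numpy 2.4.6 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9. Coordinates are given from 1 on mm10. Comparisons used the 21 main chromosomes, 1 to 19, X and Y. Read totals are not given, so depth was approached from the lists. The caller's fold and p-value fix a whole-number pileup at the summit and a background level, and these were recovered for at least 91.9% of the peaks in each library. The commonest background level stands for genome-wide depth times fragment length. It was 1.00 to 1.20 in OE libraries 1 and 4 and 4.73 to 5.38 in OE libraries 2 and 3 and both KO libraries. OE libraries 1 and 4, and 2 and 3, are thus sets of libraries defined by background and not groups of the study.

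OE peaks that shared at least 1 bp were merged, and a region was called reproducible when all 4 OE libraries supported it and no KO ChIP or KO input peak overlapped it. Overlaps were compared with 100 seeded random placements of the peaks on the same chromosomes with the same widths. Group differences of a single value were tested by exact permutation of mean log2 values over all 15 splits, two-sided, which cannot give a p under 0.0667. These permutation p-values measure only the spread between these libraries.

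Gene positions came from a RefSeq table of GRCm38.p6, whose main chromosomes have the same coordinates as mm10, limited to 21887 protein-coding genes. It has no strand or exons and no genome sequence was used here. The planned analysis therefore changed. "Near a gene end" (within 1 kb of either end of the gene) replaced the promoter, exon and intron classes. Regions were assigned to gene bodies in place of transcription start sites, up to 100 kb away. The planned search for the E-box CANNTG and for 14 other motifs at summits was not run. A gene's territory is the length of genome whose positions would be assigned to it, on a grid of 500 bp. Each of 16 gene lists (354 genes, all matched) was tested by an exact conditional test over 10 strata of territory width, two-sided, with Benjamini-Hochberg adjustment over the lists. Its p-values compare genes on a single merged set of regions and do not measure the spread between libraries. The strata correct for territory width but not for signal at gene ends in general, so a list without 5 kb around gene ends was added as an alternative after seeing the data.

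Groups, tests, gene lists, the rule for named genes and 45 alternatives were fixed before the data were examined. The rule names Twist1, the leading members of each list by mean percentile of fold over the OE libraries (4 for a list with adjusted p under 0.05, otherwise 2) and the first 2 members without a region. It also names the genes nearest the 10 strongest regions and the 5 strongest regions shared by the KO libraries, and the 10 genes with most regions. Genes named as examples of positions come from the same rule. Alternatives covered the q-value limit, the overlap that counts as shared, the number of libraries required, equal list lengths, the distance to a gene, strata and leaving out each replicate.

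The procedures were tested on simulated data. Of 9803 planted shared sites 99.9% were recovered by the region step, and all 300 planted KO sites were removed. For the gene list test over 21887 genes with randomly placed regions, 4 of 100 lists of genes with wide territories and no enrichment had p under 0.05 with strata, and 93 of 100 without. Of 100 lists in which 12 of 24 members were given a region in addition to the randomly placed ones, 100 had p under 0.05. Other members could also hold a randomly placed region. The result is therefore not the power for lists with 12 of 24 members in total. The summit pileup was recovered exactly for 100% of 5000 simulated peaks.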

Results

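Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map where the bHLH transcription factor TWIST1 sat on the genome of mouse embryonic stem cells that had been differentiated as embryoid bodies for 3 days. The overexpressing cells (OE) lacked the endogenous Twist1 gene product and carried a doxycycline-inducible, Flag-tagged Twist1. The control cells (KO) were Twist1-null without the inducible cassette and received the same treatment, 16 h of doxycycline. The series holds 9 libraries in 4 groups: 4 OE ChIP, 2 KO ChIP, 1 KO input and 2 OE inputs. Peak lists of 7 libraries were analysed here, and the OE inputs were not analysed here. The study's design text speaks of biological replicate experiments, and the KO ChIP libraries carry numbers 2 and 3. The lists held 22388, 106821, 87441 and 14160 peaks for OE libraries 1 to 4. They held 104 and 71 peaks for KO libraries 2 and 3, and 1774 for the KO input. Read totals are not given in the sources used here, so the background pileup recovered from each list stands in for depth. It was 1.00, 5.38, 5.29 and 1.20 fragments in OE libraries 1 to 4, 4.73 and 5.09 in the KO libraries and 6.46 in the input. OE libraries 2 and 3 therefore had 4.40 to 5.36 times the background of OE libraries 1 and 4. The KO libraries had 0.879 to 0.961 of the background of OE libraries 2 and 3.

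The Twist1 gene itself (chromosome 12, 33957671 to 33959831, mm10) was covered by a peak in each of the 4 OE libraries and in neither KO library nor the KO input. The strongest Twist1 peak had a fold enrichment of 41.9 in OE library 1 and 48.1 in OE library 4. In OE libraries 2 and 3 it was 4.39 and 4.45. In OE libraries 1, 3 and 4 a Twist1 peak ended at the same base, 33958598, inside the gene. The inducible Twist1 carries Twist1 sequence too, so peaks here can come from the cassette or from the endogenous locus. A peak list does not show whether the gene was deleted, so the locus does not check the knockout.

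**Figure D1:**
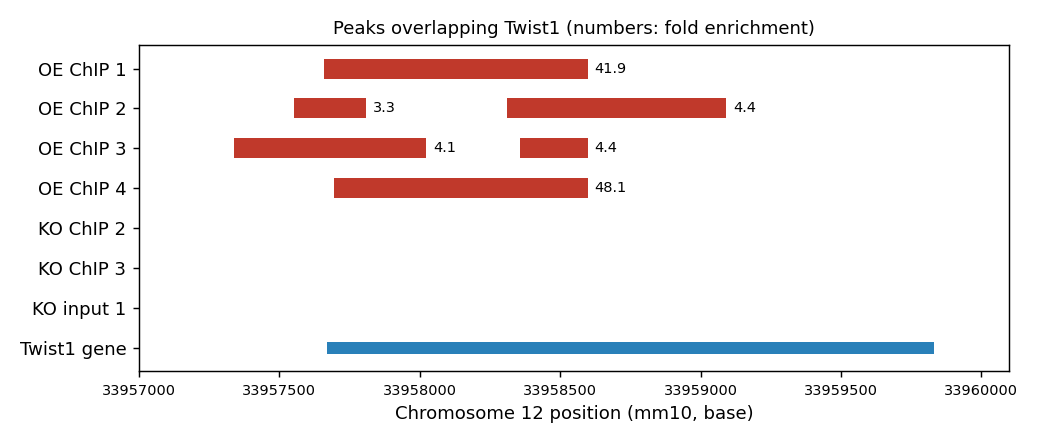
Peaks overlapping Twist1 on chromosome 12 (x axis, base position in mm10), 1 row per library, with OE ChIP in red and the gene in blue at the bottom. The number beside each bar is the fold enrichment of that peak, 41.9 and 48.1 in OE libraries 1 and 4 and at most 4.45 in OE libraries 2 and 3; KO ChIP and input have no peak here.

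The first comparison asked how much of the ChIP signal required TWIST1. On chromosomes 1 to 19, X and Y the OE libraries held 57630 ± 46341 peaks (SD, n = 4) and the KO libraries 78 ± 22.6 (SD, n = 2), a ratio of 739. Before regions with a KO or input peak were taken out, 10952 regions were found in all 4 OE libraries. Of these, 19 overlapped a KO ChIP peak and 568 a KO input peak. None of the 10 strongest of the 10952, which include those at Medag, Ndc1, Kdf1 and Sox12, overlapped either. Every OE library lay above both KO libraries, from 14078 peaks in OE library 4 to 106750 in OE library 2. The libraries with like background gave 1136 times as many peaks in OE library 2 as in KO library 2, and 1409 times as many in OE library 3 as in KO library 3. The two-sided exact permutation test of mean log2 counts over the 15 splits of the libraries into 4 and 2 gave p = 0.0667, the smallest that this design allows, so it cannot pass 0.05. On mean counts without log2, a test chosen after seeing the data, the exact permutation p was 0.133. At sites with the genome-wide background, a peak needed a fold enrichment of about 3.66 to be listed in KO library 2 and 3.62 in KO library 3, and weaker enrichment at such sites would not have been listed. In OE libraries 2 and 3, a mean of 96.2% and 96.6% of the reproducible regions described next exceeded these levels. The lowest −log10 p in a list was higher in KO (7.48 and 7.14) than in OE libraries 2 and 3 (3.67 and 3.72), and with the strictest of these limits for every ChIP library, chosen after seeing the data, the ratio was 650.

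**Figure D2:**
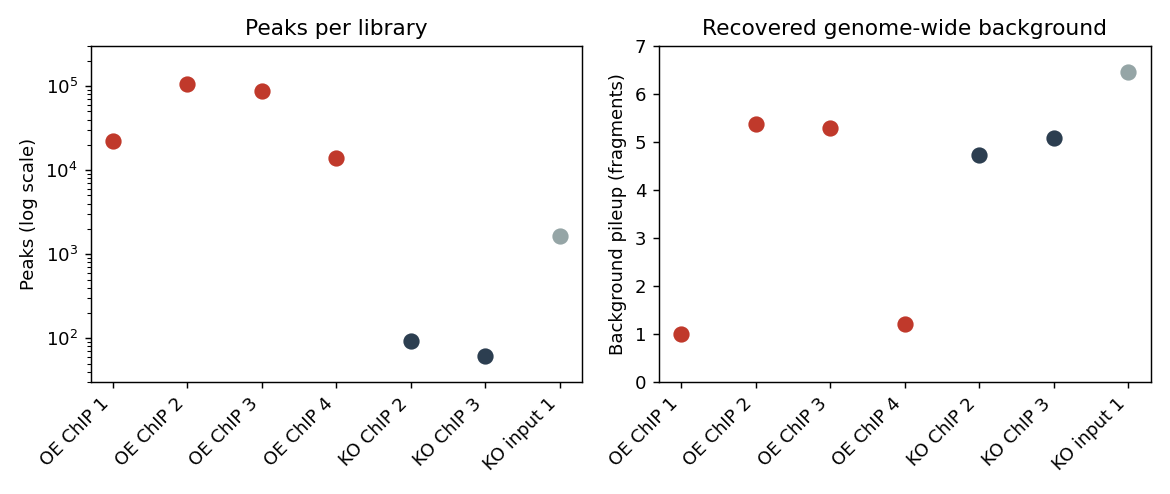
Left, peaks on chromosomes 1 to 19, X and Y in each library (log axis). Right, the background pileup of each library in fragments; every point is 1 library, OE libraries 2 and 3 and both KO libraries lie between 4.73 and 5.38, and OE libraries 1 and 4 lie at 1.00 and 1.20.

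The second comparison asked which sites TWIST1 occupied in every OE library. Ranked by mean percentile of fold over the OE libraries, the strongest such region lay inside Medag, a gene of adipocyte differentiation (chromosome 5, 149426165 to 149429886). Its fold enrichments were 744, 1699, 1699 and 576 in OE libraries 1 to 4. The next lay 1400 bp from Ndc1, which encodes a nuclear pore membrane protein (chromosome 4, 107365010 to 107368512; mean fold 760 ± 150, SD, n = 4). Then came a region inside Kdf1, a regulator of keratinocyte differentiation (chromosome 4, 133525269 to 133529242; 689 ± 221), and a region 1590 bp from Camk2n1, an inhibitor of CaM kinase II (chromosome 4, 138452117 to 138456778; 729 ± 333). The others among the 10 strongest were at or near Gm28455, the SoxC factor gene Sox12 (393 bp away), the zinc finger gene Casz1, the sialyltransferase gene St6galnac3, the tight junction gene Cldn1 (39089 bp away) and the Rac regulator gene Chn2. Their mean folds ran from 425 ± 105 at Cldn1 to 690 ± 407 at Casz1. All these folds are the authors' values for single peaks.

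Several genes carried many regions. Gse1 on chromosome 8 held 19 (1.86 would follow from the length of its territory at the genome-wide density), Kazn 11 (1.21) and the Hedgehog transcription factor gene Gli2 10 (1.95). The receptor phosphatase gene Ptprg held 10 (3.99), Zmynd8 9 (0.808), Sipa1l3 9 (1.23) and Fstl4 9 (2.77). Nav1, Prex1 and St6galnac3 held 8 each, against 1.34, 1.41 and 3.38. In all, 10375 regions were found in each of the 4 OE libraries and overlapped no KO or input peak, with a median width of 1135 bp. Before that removal there were 10952 regions of all 4 OE libraries, against 1.37 ± 1.11 after random placement of the peaks (SD over 100 placements, at most 4). Another 577 regions of all 4 OE libraries overlapped a KO or input peak and were left out. Of the 119237 merged OE regions, 37.2% came from a single library and 46.5% from 2 libraries. Between pairs of OE libraries, 84.9% to 89.1% of the shorter list was overlapped by the longer one (mean 86.6% ± 1.52, SD over 6 pairs), against 0.896% to 5.13% after random placement. Of KO peaks, made without TWIST1, a mean of 44.4% (n = 2) were overlapped by at least 2 OE libraries, also far above random placement. Exceeding random placement thus shows that lists agree, not that TWIST1 bound there. The number of regions depended on the libraries required, and was 18677 for at least 3 of 4, 73780 for at least 2 of 4 and 17365 without OE library 4. It was 5183 with equal list lengths, 6455 at −log10 q of at least 10 and 6454 with summits within 100 bp, and 72156 with OE libraries 2 and 3 alone, chosen after seeing the data.

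The strength of the regions was shared within pairs of libraries more than across all 4. Tfcp2l1, Fgf15 and Sox9 had high folds in every OE library. The best region of Prrx2, a paired-related homeobox gene, had folds of 426 and 255 in OE libraries 1 and 4 and of 38.6 and 31.9 in OE libraries 2 and 3. At Id2 the folds were 92.3 and 55.8 against 11.9 and 13.98. At Sox2 they were 36.9 and 34.96 against 220 and 127, but Tfcp2l1 had a like gap (247 and 163 against 837 and 1002). Prrx2, Id2 and Sox2 all ranked high within the lists (mean percentiles 98.4, 92.8 and 96.7). Their gaps in fold are therefore not read as differences between the sets. Across the 10375 regions, which are not independent replicates, Spearman's rho of fold enrichment was 0.865 between OE libraries 1 and 4 and 0.966 between OE libraries 2 and 3. The other 4 pairs gave 0.170 to 0.253, and the mean over all 6 pairs was 0.448 ± 0.365 (SD). The libraries that ranked alike were those with like background. Summits lay within 100 bp of each other for 76.5% of the shorter list between OE libraries 1 and 4 and for 71.5% between 2 and 3, and for 53.5% to 57.8% in the other pairs.

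**Figure D3:**
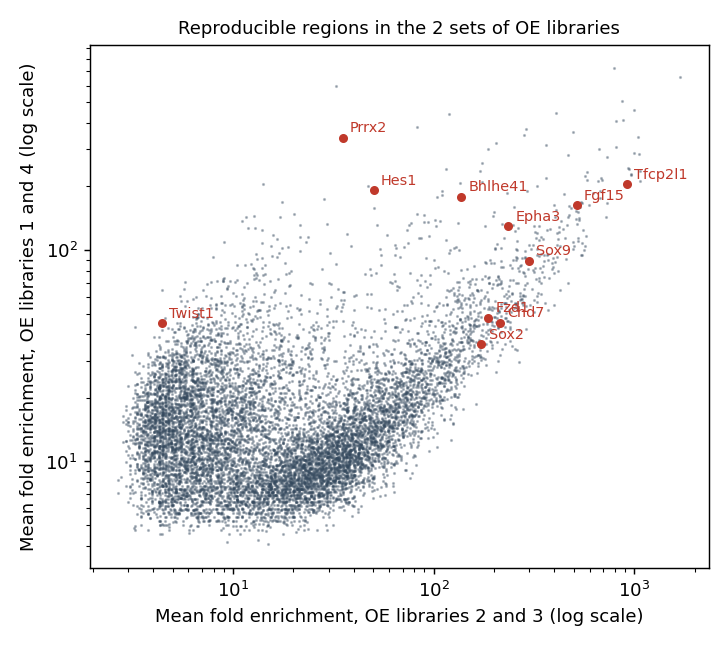
Each point is 1 of the 10375 reproducible regions, placed by its mean fold enrichment in OE libraries 2 and 3 (x axis) and in OE libraries 1 and 4 (y axis), both on log scales. Named points are Twist1 and the best region of the leading gene of each list that passed its test. Twist1 ranks at percentiles 89.4 and 95.9 in the lists of OE libraries 1 and 4. In those of OE libraries 2 and 3 it ranks at 9.73 and 8.47. Prrx2 and Hes1 have higher folds in OE libraries 1 and 4 but high mean percentiles over the 4 lists (98.4 and 98.8).

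The third comparison placed the peaks relative to protein-coding genes. Reproducible regions lay close to the ends of genes such as Fzd2, Hes6, Lfng, Isl1 and Prox1: 30.9% had their summit within 1 kb of either end of a gene, 9.71 times the 3.18% given by random placement. The share was 16.1% for the regions of OE libraries 2 and 3 alone and 9.66% for the 10375 strongest of those, both chosen after seeing the data. A further 35.3% lay deeper inside genes (random 38.9%) and 33.8% lay between genes (random 57.9%). Counting those near gene ends, 5923 regions (57.1%) lay inside a gene body, as at Pax3, Gli2, Zeb2 and Epha3, and regions outside genes were a median of 17.8 kb from one. Exons, introns and strand were not analysed here. Among OE libraries the share near gene ends was 25.3% and 33.0% in libraries 1 and 4 and 14.5% and 16.4% in libraries 2 and 3 (mean 22.3% ± 8.53, SD, n = 4). It was 10.6% and 6.45% in KO libraries 2 and 3, with p = 0.133 for OE against KO by exact permutation, two-sided. The KO input list had 41.4% of its peaks near gene ends, 13.1 times the 3.17% given by random placement. An excess near gene ends is thus not particular to TWIST1 ChIP. Between genes lay 38.9% ± 4.44 of OE peaks (n = 4) and 68.5% ± 8.08 of KO peaks (n = 2), with an exact permutation p = 0.0667. The share deeper inside genes was 38.8% ± 4.16 in OE and 22.98% ± 5.12 in KO, also with an exact permutation p of 0.0667 over 15 splits. The KO shares rest on 94 and 62 peaks, of which 20 and 19 lay in a stretch of chromosome 4 and 12 and 9 on Y. Between genes lay 62.8% and 74.2% of them, against 61.9% and 63.2% after random placement. The contrast with OE thus cannot be credited to TWIST1.

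The fourth comparison asked which gene groups lay near the reproducible regions. Each region was given to the gene that held it, or else to the nearest gene within 100 kb, and 6511 of 21887 protein-coding genes (29.7%) received at least 1. Of 16 gene lists, 10 had more members with a region than genes with territories of like width (exact conditional test, two-sided, Benjamini-Hochberg adjusted over the 16 lists). The 14 alternatives given with each list include a test without strata, which all 10 passed. It gave the lowest p quoted for neural crest, mesenchyme, WNT, FGF, chromatin and cell migration genes. Without strata, 93 of 100 simulated lists of wide genes with no enrichment had p under 0.05, so passing that alternative is weak evidence. Of 17 genes for bHLH partners and inhibitors, the list with the highest ratio, 13 had a region against 5.49 expected (adjusted exact p = 0.00143, and 0.000574 to 0.244 over 14 alternatives, 11 of which it passed). Bhlhe41, Id1, Hes6 and Id2 led it, with mean folds of 158 ± 27.3, 230 ± 157, 105 ± 68.4 and 43.5 ± 38.3 (SD, n = 4). The E-protein genes Tcf3, Tcf4 and Tcf12, dimer partners of TWIST1 chosen here after their values were seen, had 1, 2 and 2 regions. Lyl1 and Msc had none. Among Notch signalling genes 14 of 18 had a region against 6.08 expected (adjusted exact p = 0.00143, and 0.000113 to 0.243 over 14 alternatives, 11 of which it passed). The best region of the effector gene Hes1 lay 56306 bp away from it with a mean fold of 121 ± 96.4, and those of the receptor gene Notch1 and the modifier gene Lfng had 166 ± 125 and 70.8 ± 29.7. The best region of Hes3 had 37.6 ± 11.4, and Hey1 and Hey2 had no region.

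Genes of stem cells and of early neural fate were also enriched. Of 21 pluripotency genes, 14 had a region against 6.93 expected (adjusted exact p = 0.00912, and 0.000747 to 0.0912 over 14 alternatives, 11 of which it passed). Tfcp2l1 led with 562 ± 419 at chromosome 1, 118758154 to 118760975, 74272 bp from the gene, followed by the Nodal inhibitor gene Lefty1 (95.6 ± 52.5), Fgf4 (122 ± 100.0) and Tbx3 (29.4 ± 8.20). Klf2 and Klf5 had none. The region given to Tfcp2l1 lies between that gene, which ends at 118685168, and Gli2, which starts at 118834061. It is about as far from Gli2 as from Tfcp2l1, so it could as well be counted with Gli2. Of 24 neural progenitor and neurogenic genes 16 had a region against 8.39 expected (adjusted exact p = 0.00912, and 4.53e-05 to 0.512 over 14 alternatives, 10 of which it passed), led by Sox2 (105 ± 87.9, 20376 bp away), Lhx2 (33.9 ± 5.15), Pou3f1 (63.0 ± 44.3) and Neurog1 (23.5 ± 12.2). Pax6 and Sox3 had none.

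Neural crest and mesenchymal genes, from tissues in which TWIST1 is best known, followed. Of 24 genes for mesenchyme and epithelial-mesenchymal transition 17 had a region against 9.70 expected (adjusted exact p = 0.0121, and 0.000411 to 0.406 over 14 alternatives, 12 of which it passed). Prrx2 and Snai3 had mean folds of 188 ± 190 and 54.5 ± 31.8. The fibronectin gene Fn1, whose region lay 87933 bp away, and Zeb2 had 84.2 ± 53.8 and 70.6 ± 40.1. Zeb1 and the vimentin gene Vim had none. Of 18 neural crest specification genes 13 had a region against 7.80 expected (adjusted exact p = 0.0396, and 0.00111 to 0.406 over 14 alternatives, 8 of which it passed). Sox9 (194 ± 122 at chromosome 11, 112784438 to 112787388, over the gene) and Sox5 (167 ± 114) led, with Pax3 (76.9 ± 40.0) and Ets1 (47.6 ± 25.4) after them. Zic1 and Msx1 had none. Cell migration and guidance genes had a region in 22 of 28 cases against 14.5 expected (adjusted exact p = 0.0147, and 4.15e-06 to 0.291 over 14 alternatives, 11 of which it passed), among them the ephrin system genes Epha3 (182 ± 64.9), Efna5 (238 ± 182) and Ephb2 (114 ± 41.0) and the guidance cue gene Slit1 (107 ± 59.1). Sema3d and Nrp1 had none.

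Signalling and chromatin genes made up the rest of the lists that passed. FGF signalling genes had a region in 14 of 21 cases against 8.29 expected (adjusted exact p = 0.0367, and 0.00164 to 0.281 over 14 alternatives, 8 of which it passed). Fgf15 (340 ± 205), the inhibitor gene Spry4 (180 ± 123), the receptor gene Fgfr2 (79.4 ± 52.3) and Etv5 (44.5 ± 19.1) led it, and Fgf3 and Fgf10 had none. WNT signalling genes had a region in 16 of 24 cases against 10.2 expected (adjusted exact p = 0.0396, and 0.00107 to 0.452 over 14 alternatives, 7 of which it passed). Fzd1 (118 ± 88.3, 67185 bp away), Lef1 (61.6 ± 41.5, 75316 bp away), Fzd2 (28.1 ± 5.598) and Wnt7b (16.2 ± 7.61) led it, and Wnt1 and Wnt3a had none. Chromatin regulator genes of the CHD, NSD and related families had a region in 14 of 21 cases against 8.59 expected (adjusted exact p = 0.0396, and 0.00164 to 0.695 over 14 alternatives, 4 of which it passed). Chd7 (130 ± 97.8, 89541 bp away), Chd9 (73.4 ± 49.1), Kmt2a (28.6 ± 17.1) and Smarca2 (64.1 ± 57.3) led it, and Chd4 and Chd8 had none.

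Other lists did not pass in the main test. Craniofacial and skeletal patterning genes had a region in 13 of 24 cases (adjusted exact p = 0.400, and 0.0110 to 1 over 14 alternatives, 3 of which it passed), Sox11 and Hand2 among them, and Alx1 and Hand1 had none. BMP and TGF-beta signalling genes had 12 of 24 (adjusted exact p = 0.718, and 0.0465 to 1 over 14 alternatives, 1 of which it passed), with Bmp7 and Smad3 leading and none at Bmp2 and Bmp5. Mesoderm and heart genes had 10 of 24 (adjusted exact p = 0.763), with Tcf15 and Isl1 leading and none at Brachyury and Mixl1. Endoderm and liver genes had 5 of 20, among them Prox1 and Cdx2 and not Foxa2 and Foxa3. Blood and immune genes had 5 of 22, with Itgam and Runx1 and without Tal1 and Gata1, and both of these lists had an adjusted p of 0.763. Housekeeping genes had 9 of 24 against 4.95 expected (ratio 1.82, adjusted exact p = 0.112, and 0.0122 to 1 over 14 alternatives, 1 of which it passed), with Rpl13a and Ywhaz leading and none at Actb and Gapdh. This ratio was above those of mesenchyme (1.75), FGF signalling (1.69), neural crest specification (1.67), chromatin regulators (1.63), WNT signalling (1.57) and cell migration (1.52), which passed. For these lists, passing does not show a larger excess than at housekeeping genes.

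The list results moved with the regions and libraries used. With regions over 5 kb from any gene end alone, which number 5706 and reach 14.8% of genes, cell migration and guidance passed (ratio 1.77, adjusted exact p = 0.0334) and the other 9 lists did not. Their ratios were 1.49 to 2.49, against 1.57 to 2.37 in the main test, with pluripotency at 2.49 (adjusted exact p = 0.0506) and bHLH partners at 2.00 (0.244). With regions of at least 2 of the 4 libraries, which reached 74.5% of all genes, 0 lists passed this exact test and 8 had an unadjusted p under 0.05. OE libraries 1 and 4 alone kept 9 of the 10 lists and lost neural crest specification (ratio 1.52 against 1.67 in the main test, adjusted exact p = 0.0816). OE libraries 2 and 3 alone, whose 72156 regions reached 73.9% of all genes, kept 5 of the 10. There bHLH partners (adjusted exact p = 0.138), Notch signalling (0.155), neural crest specification (0.105), chromatin regulators (0.0622) and cell migration (0.256) were lost, while craniofacial patterning and BMP and TGF-beta signalling were gained (both 0.0465). With the 10375 strongest of these regions, 6 of the 10 passed: bHLH partners (adjusted exact p = 0.00835), Notch signalling, neural crest specification and cell migration (each 0.0210), mesenchyme (0.00117) and pluripotency (0.000747). Craniofacial patterning then had a ratio of 0.657 and did not pass. Leaving out OE library 4 lost FGF signalling (ratio 1.30, adjusted exact p = 0.281) and cell migration (1.26, 0.102), against main ratios of 1.69 and 1.52. It gained housekeeping (adjusted exact p = 0.0122) and craniofacial patterning (0.0110). Without OE library 3, WNT signalling (ratio 1.55, adjusted exact p = 0.0504) and chromatin regulators (1.49, 0.131) were lost. Without OE library 1, chromatin regulators were lost (ratio 1.57, adjusted exact p = 0.0585). Their ratios in the main test were 1.57 for WNT signalling and 1.63 for chromatin regulators, so the ratios moved little. The tests far from gene ends, with pairs of libraries and with the strongest regions were chosen after seeing the data.

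**Figure D4:**
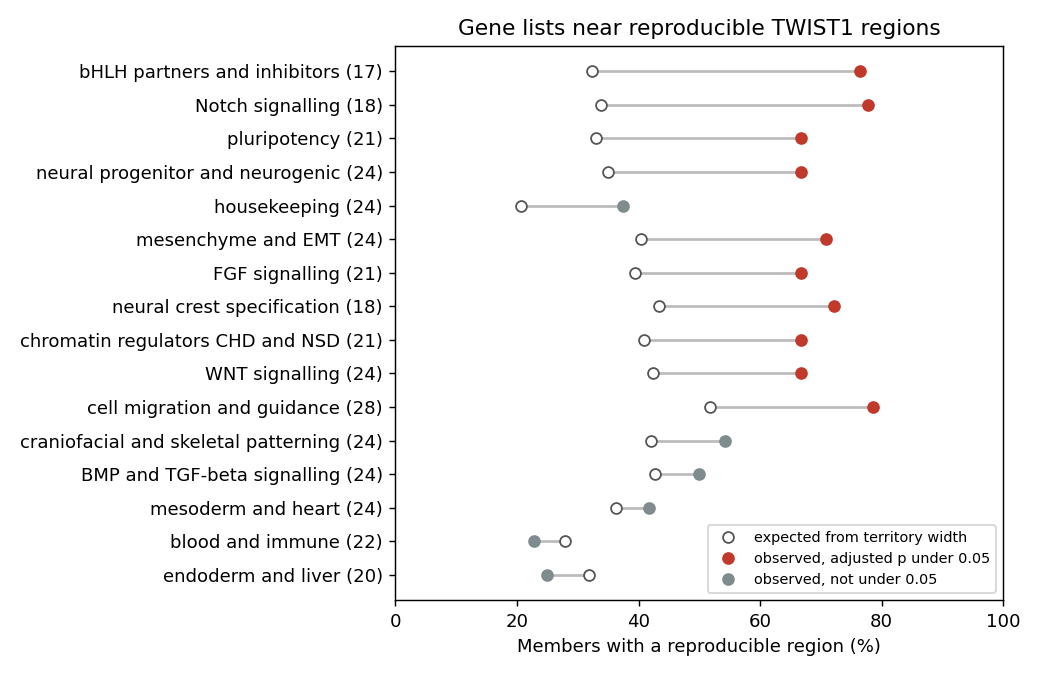
Percent of the members of each list that had a reproducible region (filled points) and the percent expected from genes with territories of like width (open points); the number of members is in parentheses. Red marks the 10 lists with adjusted p under 0.05, from cell migration and guidance at 78.6% to pluripotency at 66.7%, and endoderm and liver lies lowest in ratio at 25% against 31.8%.

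The last comparison asked where the antibody enriched DNA without TWIST1. Ranked by mean percentile of fold over the KO libraries, the strongest peak shared by both lay inside Gm32584 (chromosome 5, 36630467 to 36630771). It had folds of 18.7 and 15.8 and no peak in any OE library. A peak inside Msi2, which encodes an RNA-binding protein (chromosome 11, 88380259 to 88380866), had 34.3 and 14.1 in the KO libraries and 9.25 and 6.20 in OE libraries 2 and 3. A peak 453 bp from the primitive streak gene Mixl1 (chromosome 1, 180696973 to 180697758) had 19.7 and 12.5 in KO and 6.43, 4.93 and 6.81 in OE libraries 2, 3 and 4. The next in strength were on Y, at 260926 to 261588 and, nearest to LOC665918, at 145352 to 146181. None of the 5 had a peak in the KO input. Of the KO peaks, 46.8% of 94 in library 2 and 41.9% of 62 in library 3 were overlapped by peaks of at least 2 OE libraries (mean 44.4% ± 3.45, SD, n = 2), against 2.78% and 2.65% after random placement. The input list overlapped 25.5% and 29.0% of them. In KO libraries 2 and 3, 44 and 26 peaks were shared with OE, 24 and 18 with the input, 46 and 27 with either and 48 and 35 with neither. Many KO peaks shared with OE thus also had an input peak, and enrichment there cannot be credited to the antibody. A stretch of chromosome 4, from 145433604 to 147586201, held 20 and 19 of the KO peaks, the most in any 3 Mb outside Y, and chromosome Y held 12 and 9. The same 3 Mb held 183 and 149 peaks in OE libraries 2 and 3 and 76 in the KO input.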

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

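Among 83 values compared across the 4 OE libraries, 2 had one library far from the others, and chance alone gives such a gap in about 1 of 20 groups. The median peak width was 482 bp in OE library 3 against 412, 415 and 420 bp in OE libraries 1, 2 and 4. The narrowest peak was 195 bp in OE library 2 against 227, 227 and 225 bp in OE libraries 1, 3 and 4.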

How the results depend on the processing

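The common −log10 p limit and the alternatives with OE libraries 2 and 3 or 1 and 4 alone, 20 strata, the strongest regions of libraries 2 and 3, and regions far from gene ends were chosen after seeing the data. The ratio of peak counts stayed between 529 and 930 without any single library and was 650 with a common −log10 p limit and 1265 with the replicate block of numbers 2 and 3. Reproducible regions numbered 6455 at −log10 q of at least 10, 6454 with summits within 100 bp, 18677 and 73780 for 3 and 2 of 4 libraries, 5183 with equal list lengths and 72156 with OE libraries 2 and 3 alone. Leaving out 1 library gave 10555 to 17365, the highest without OE library 4, whose list is the shortest. Pairwise overlap was 83.3% at 50% of the shorter peak, 61.5% for summits within 100 bp, 59.2% at equal lengths, 83.8% at −log10 q of at least 10 and 85.5% to 87.3% without 1 library. At −log10 q of at least 5, 48.5% of KO peaks were shared with OE. Within 5 kb of gene ends lay 38.6% of OE peaks. Rank agreement stayed between 0.424 and 0.485 in all 6 alternatives. Leaving out any library keeps the same mix of pairs within and across the 2 sets, so the steady mean there says little about agreement. Lists passing numbered 6 up to 1000 kb, 0 for at least 2 of 4 libraries, 4 for summits within 100 bp, 6 for the strongest OE 2 and 3 regions, 1 over 5 kb from gene ends, and 8 to 10 without 1 library. Lost lists still had ratios of 1.34 to 2.03 for summits within 100 bp, where fewer regions were tested, and of 1.49 to 2.49 over 5 kb from gene ends. Of the 10 lists, 8 remained without OE library 4, 5 with OE libraries 2 and 3 alone, which reach 73.9% of genes, and 6 with the strongest of those regions, among them bHLH partners, Notch, neural crest and cell migration. Calls gained in other lists are given with those lists.

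Ratios crossed 1 in lists that had not passed: craniofacial 0.996 (summits within 100 bp) and 0.657 (strongest OE 2 and 3 regions); mesoderm and heart 0.672 and 0.518 likewise and 0.776 over 5 kb from gene ends. Endoderm and liver gave 1.05 up to 10 kb, 1.04 for at least 2 libraries and 0.750 to 1.05 without 1 library, above 1 without OE library 4. Blood and immune gave 1.00 for at least 2 libraries, 1.01 for summits, 1.01 for OE libraries 2 and 3 and 1.00 over 5 kb. The smaller counts at stricter limits follow from their construction, and the cause of other changes was not tested. The 10 E-box alternatives were not run, as no sequence was used here. KO libraries list no enrichment below about 3.62 at sites with the genome-wide background.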

Other observations

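The tests of gene ends, of the Twist1 locus and of halved signal together with fewer genes on X were chosen after seeing the data, and the other tests below before their values were seen. Chromosome X held few regions: 205, or 1.20 per Mb against 4.18 per Mb on the autosomes, a ratio of 0.287. The lowest single autosome had a ratio of 0.679. Y held 2. Of 7 genes of the gene lists on X, Efnb1, named here after its values were seen, had 2 regions (best mean fold 51.7 ± 36.2, SD, n = 4), and the other 6, Sox3 and Gata1 among them, had none.

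OE libraries 1 and 4 held fewer peaks than OE libraries 2 and 3. Lower depth as the whole cause is argued against: thinning libraries 2 and 3 to the background of libraries 1 and 4 predicted 2.70 times the observed peaks (median of 4 pairings). At least 30.0% of peaks predicted to be called were missing in every pairing. Any cause of fewer peaks leaves peaks missing, so this share cannot tell whether different sites were enriched in the 2 sets. Of the peaks of libraries 1 and 4, 85.4% to 87.5% were overlapped by peaks of libraries 2 and 3. Different sites thus stay open, with lower depth still a possible part. The share of regions within 1 kb of a gene end was 8.22 times as high in the 2593 regions ranked relatively highest in libraries 1 and 4 (67.5%) as in the 2594 ranked relatively lowest (8.21%), but the higher gene-end share of libraries 1 and 4 had been seen before this test, which does not show why they hold fewer peaks, so a preference for gene ends stays open. The sets also part on 6 unplaced sequences, where libraries 1 and 4 had 45 and 51 peaks and libraries 2 and 3 had 0, so a difference in sequencing, alignment, peak calling or its control stays open too and was not tested, and no biological explanation was tested, since the labels give no difference between the sets.

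The Twist1 gene had folds of 41.9 and 48.1 in OE libraries 1 and 4, and 1 or a few genomic copies of the cassette would not raise coverage so far (lowest fold 41.9). In OE libraries 2 and 3 the fold was at most 4.45, between the limit of 4 set for a few extra copies and the 10 set to exclude them, so copies and weak binding cannot be told apart there. Whether DNA fragments ending at a fixed base, as from a plasmid or an amplified coding sequence, contributed stays open, also in OE library 3. The Twist1 peaks of OE libraries 1 and 4 both ended at 33958598, as did a Twist1 peak of OE library 3. Of all overlapping peaks of OE libraries 1 and 4, 1.21% share an end. The shared end at Twist1 is, however, what raised the question. Binding at Twist1 like that at other regions stays open: its rank difference between the sets lay at the 99.9 percentile of 3204 regions near gene ends, and 2 of them had one as large.

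For the low density on X, a single X copy halving the signal predicted a ratio at least 1.90 times that seen in OE libraries 2 and 3, and fewer genes do not account for it alone (0.431 as many regions per gene as on autosomes). Both together predicted 1.26 and 1.39 times the observed ratio in OE libraries 2 and 3 and 1.50 and 1.64 times in OE libraries 1 and 4, on both sides of the limit of 1.5, so whether they suffice stays open. The number of X copies in these cells is not given in the sources used here, and read mapping on X was not tested. No biological explanation was tested, since no group of the study bears on it.

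Outside the main chromosomes the OE libraries held 80, 71, 56 and 82 peaks, the KO libraries 10 and 9 and the KO input 132. On the 6 unplaced sequences that part the sets of OE libraries, the KO input had 41 peaks and both KO libraries had 0.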
